A study of Homo sapiens with 16 samples.

How the data were processed

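RNA of SH-SY5Y cells, an established human neuroblastoma line, was measured on 16 single-colour Agilent oligonucleotide arrays, each with 62976 spots. Per the labels, cells were grown for 48 h in serum-containing medium (day 0, n = 2) and then for a further 48 h (day 2) with vehicle (n = 2) or with ILB at 0.01, 0.1, 1 or 10 µg/ml (n = 3 each). The labels give ILB by this name alone and do not say what it is. They also do not say whether replicates of a group came from independent cultures, so the p-values below measure the spread between these samples. Cells had been kept in RNAlater, RNA had been extracted with an Agilent kit, and Cy3-labelled cRNA had been made from 0.5 µg of RNA.

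Each deposited scanner file held the intensity values of Agilent Feature Extraction 12.1.0.3 (protocol GE1_1200_Jun14, per the file headers): a processed signal on the linear scale after background subtraction and detrending within the array, the median signal of each spot and of its local background, and 0 or 1 marks for outlying, saturated and well-above-background spots. The deposited series matrix held linear intensity values equal to the processed signal of each scanner file (largest absolute log2 ratio 0.0072), with no normalization between arrays. The file headers named array design 072363 and the labels named 028004; probe identities were taken from the scanner files. Official gene symbols came from the RefSeq accession that a scanner file gave for a probe, which named 34892 of 58201 probes and 25006 symbols. Transcripts without a symbol kept the name in the scanner files.

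In the main processing, 2075 control spots and the spots marked as outliers were left out, the processed signal was taken to log2, and spots of 1 probe were averaged (300 probes were spotted 10 times each). From each array the 75th percentile over the 20580 probes well above background on all 16 arrays was subtracted. That reference was chosen by a rule fixed in advance, because a mean of 45.2% of probes per array was well above background. Probes well above background on every array of at least 1 group were kept (27854 probes), and each gene was represented by its brightest probe, which left 22025 genes, 15725 of them with a symbol. For 297 of these genes a value was missing on at least 1 array. No spot was saturated. Signal over background, the array's counterpart of depth, is given with the samples in the results; the number of arrays limits the precision of every comparison.

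Group means were compared with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, jsonlite version 2.0.0), with 1 fit to all 16 arrays and moderated statistics (10 residual and 1.34 prior degrees of freedom). P-values were two-sided and were adjusted by the Benjamini-Hochberg method over the 22025 genes of a comparison, and a gene passed at an adjusted p of 0.05. There were 10 comparisons: vehicle at day 2 against day 0, each of the 4 ILB doses against vehicle, 10 against 1 µg/ml, 0.1 against 0.01 µg/ml, the mean change for a 10-fold dose step within slides, both low doses against day 0, and both high doses against both low doses. Because 5 comparisons use the same 2 vehicle arrays, the overlap of their results was set beside 20 simulated data sets in which no group differed. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. There were 30 gene lists, each with at least 5 tested members, and 300 list tests, adjusted over the 30 lists of a comparison.

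Named genes followed a rule: among genes with an official symbol that passed, were well above background on all arrays of the higher group and did not overlap between groups, the 10 largest rises and 10 largest falls in the comparisons of vehicle with day 0 and of 10 µg/ml with vehicle, and 5 and 5 in the others. From each list called by camera, up to 4 members with the smallest p among those moving in the list's direction were added, taken from members that had passed. The main processing, the comparisons, the gene lists, this rule and most alternatives were chosen before the data were examined. Where every array of the lower group was below the limit for well above background, the change is given as "at least N-fold": the mean of the higher group over the lower group's values, each raised to the dimmest well-above-background signal of its array. Other values marked ± are log2 fold changes with the limma standard error.

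The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Between 74% and 92% were recovered, with 6 to 15 calls among 21494 unchanged genes. Alternatives covered normexp background correction (median spot and local background signals, offset 50), quantile and median scaling, the 75th percentile over all probes, no filter or a stricter filter on dim probes, the mean over a gene's probes, array weights, a variance trend, slide row or replicate number as a block, a 2-fold minimum, the deposited series matrix, leaving out each array, and fits to the groups of a comparison alone. Chosen after the data were seen were fits to the arrays of 1 slide only, the removal of a streak of dark spots from 1 array, quantile scaling without 1 outlying array, and, for the gene lists, normexp correction and leaving out that array.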

Results

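The arrays held 6 groups of SH-SY5Y neuroblastoma cells: day 0 (n = 2), vehicle at day 2 (n = 2), and ILB at 0.01, 0.1, 1 and 10 µg/ml at day 2 (n = 3 each). They lay on 2 slides of 8 arrays. Slide 1 held day 0 and both low doses (0.01 and 0.1 µg/ml), and slide 2 held both high doses (1 and 10 µg/ml) and vehicle. Slide and group thus cannot be told apart between vehicle and day 0 or a low dose, or between high and low doses. The share of probes well above background ranged from 36.8% to 49.4% on 15 arrays and was 67.8% on ILB 0.1 replicate 2, whose median signal was 34.4 against 5.24 to 8.36 on the other arrays. Among the 22025 genes tested, 13453 were protein-coding, 1633 were long non-coding RNA genes, 224 were small nucleolar RNA (snoRNA) genes and 6300 were transcripts without a symbol. The 75th percentile used for scaling ranged from a signal of 1010 to 1290.

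**Figure D1:**
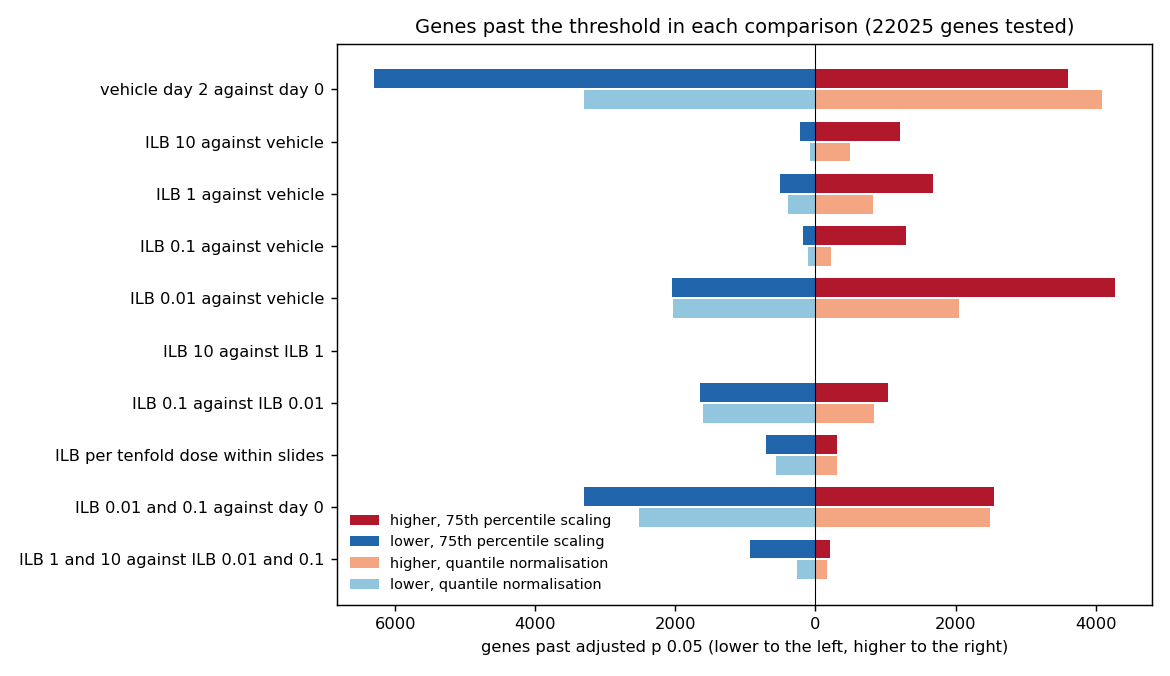
Number of genes past an adjusted p of 0.05 in each comparison (x axis, lower to the left and higher to the right), with scaling to the 75th percentile (dark bars) and with quantile normalization (light bars). Vehicle against day 0 had the most genes by either scaling (9913 and 7391), and 10 against 1 µg/ml had 1 and 2.

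The first comparison gives the change over 48 h without ILB (vehicle, n = 2, against day 0, n = 2). The largest rises were in EGFLAM, a matrix protein of the pikachurin type (3.46 ± 0.24, or 11.04-fold, adjusted p = 1.5e-06), and in H19, an imprinted non-coding RNA (3.36 ± 0.09, or 10.29-fold). IGF2, the imprinted insulin-like growth factor gene beside H19, rose 7.72-fold (2.95 ± 0.09, adjusted p = 3.3e-09). SUSD2, a membrane protein, rose 8.11-fold (3.02 ± 0.09), the natriuretic peptide NPPA rose 5.71-fold (2.51 ± 0.07), and the heparan sulfate 3-O-sulfotransferase HS3ST2 rose 5.61-fold (2.49 ± 0.1). CBLN4, a synapse organiser (2.36 ± 0.1), and GDF10, a ligand of the TGF-beta family (2.34 ± 0.11), rose as well. Among the largest falls in the fit were the focal adhesion protein LPP (at least 3.41-fold, adjusted p = 4.4e-06), the adrenergic receptor ADRA2A (-3.79 ± 0.52), the BMP regulator BMPER (-3.51 ± 0.5), and the collagen COL6A6 (at least 4.81-fold). The vasoconstrictor peptide EDN1 (-3.43 ± 0.21, or 10.79-fold lower, adjusted p = 6.8e-07) and the neurotrophin-3 receptor NTRK3 (-3.35 ± 0.3) were lower. NRG1-IT3, PRR20B and GASK1B also fell, by at least 4.79-fold, 5.8-fold and 2.8-fold. WNT7A, a secreted signalling protein, rose at least 1.61-fold (adjusted p = 0.0074), FA2H, a fatty acid hydroxylase, rose at least 2.2-fold (adjusted p = 0.041), and NUGGC fell at least 4.26-fold (adjusted p = 0.016). These 3 calls were each lost without day 0 replicate 1.

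Lists of energy metabolism, biosynthesis, protein quality and cell cycle genes were called up over this interval. In oxidative phosphorylation, the mitochondrial machinery that makes ATP, 39 of 50 measured members rose and 11 did not pass (41 rose adjusted over the list alone; camera adjusted p = 1e-14), among them SDHB (0.7 ± 0.05), ATP5F1B (0.67 ± 0.06) and COX4I1 (0.63 ± 0.06). Of the proteasome, the complex that degrades tagged proteins, 23 of 31 members rose and none fell (27 rose adjusted over the list alone; camera adjusted p = 1.6e-11), including PSMB5 (0.51 ± 0.05) and PSMA5 (0.51 ± 0.06). The cytosolic heat shock response, the chaperone genes, had 16 rises, 1 fall and 2 members that did not pass, with the same counts of 16 and 1 adjusted over the list alone (camera adjusted p = 7e-11). HSPA1A rose by 1.08 ± 0.04 and HSPE1 by 0.57 ± 0.04. Cholesterol biosynthesis and uptake had 18 rises, no fall and 6 members that did not pass (18 adjusted over the list alone; camera adjusted p = 6.4e-10). TM7SF2 stood at 0.72 ± 0.06 and ACAT2 at 0.57 ± 0.05. In the amino acid and integrated stress response, 20 rose, 3 fell and 10 did not pass (21 and 3 adjusted over the list alone; camera adjusted p = 1.6e-08). DDIT4, an inhibitor of growth signalling, rose by 0.87 ± 0.06 and the serine synthesis enzyme PSAT1 by 0.61 ± 0.05. Glycolysis had 13 rises, 2 falls and 1 member that did not pass (13 and 2 adjusted over the list alone; camera adjusted p = 6.2e-07), led by ALDOC (0.93 ± 0.07) and PGK1 (0.63 ± 0.05). Fatty acid synthesis and desaturation had 9 rises, 1 fall and 5 that did not pass (10 and 2 adjusted over the list alone; camera adjusted p = 0.00063). SREBF1, its transcriptional regulator, stood at 0.65 ± 0.05 and SCD at 0.76 ± 0.09. In G1/S and DNA replication 14 rose, 2 fell and 18 did not pass (15 and 3 adjusted over the list alone; camera adjusted p = 0.00039). GINS2 stood at 0.44 ± 0.06. Mitosis had 16 rises, 4 falls and 14 that did not pass (16 and 4 adjusted over the list alone; camera adjusted p = 0.0012). CCNB1, the mitotic cyclin, stood at 0.37 ± 0.04. These 9 lists were also called with an estimated correlation, but G1/S and mitosis not after quantile normalization (adjusted p = 0.057 and 0.17).

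The noradrenergic neuroblastoma and neuronal lists were called up with members moving both ways, and those of matrix, TGF-beta and mesenchymal genes down. With quantile normalization the former pair was not called (adjusted p = 0.37 and 0.16). Adrenergic neuroblastoma identity had 8 rises, 4 falls and 10 members that did not pass, with the same 8 and 4 adjusted over the list alone (camera adjusted p = 0.019, and 0.13 with an estimated correlation). The granule protein CHGB rose by 1.64 ± 0.06 and DBH, the enzyme that makes noradrenaline, by 1.32 ± 0.09. Neuronal differentiation and synapse had 11 rises, 8 falls and 11 that did not pass, the same 11 and 8 adjusted over the list alone (camera adjusted p = 0.025, and 0.048 with an estimated correlation). The microtubule protein MAPT stood at 1.03 ± 0.1 and TUBB3 at 0.53 ± 0.05. TGF-beta and BMP targets fell (1 rise, 13 falls, 7 that did not pass, and 15 falls adjusted over the list alone; camera adjusted p = 7.1e-05). The inhibitory SMAD6 stood at -1.93 ± 0.07, ID2 at -1.49 ± 0.06 and ID1 at -1.26 ± 0.06. Extracellular matrix genes had 1 rise, 19 falls and 9 that did not pass (2 and 21 adjusted over the list alone; camera adjusted p = 0.00026), among them the fibrillar collagens COL3A1 (-1.5 ± 0.11) and COL5A1 (-1.3 ± 0.06). Fibroblast markers, of which 10 of 12 were expressed in these cells, had 1 rise, 7 falls and 2 that did not pass (9 falls adjusted over the list alone; camera adjusted p = 0.0052). DCN, the proteoglycan decorin, stood at -1.29 ± 0.06. Mesenchymal neuroblastoma identity had 1 rise, 11 falls and 5 that did not pass, 11 falls adjusted over the list alone (camera adjusted p = 0.0071). The transcriptional coactivator YAP1 stood at -0.81 ± 0.07 and VIM at -0.65 ± 0.07. These 4 falling lists were also called with an estimated correlation. Of the epithelial markers, 6 of 12 of which were expressed, 5 fell and none rose, 5 adjusted over the list alone (camera adjusted p = 0.014, and 0.066 with an estimated correlation). The keratin KRT18 stood at -0.99 ± 0.09. Cytosolic ribosomal proteins had 14 rises, 5 falls and 32 that did not pass, 14 and 5 adjusted over the list alone (camera adjusted p = 0.0066, and 0.53 with an estimated correlation). RPS3 stood at 0.73 ± 0.07. Apoptosis regulators had 13 rises, 6 falls and 14 that did not pass, 13 and 6 adjusted over the list alone. HRK, a pro-apoptotic protein, stood at 1.61 ± 0.06. The hypoxia response had 10 rises, 5 falls and 10 that did not pass (11 and 5 adjusted over the list alone). P4HA2 stood at 0.61 ± 0.08. Both were called up by camera (adjusted p = 0.025 each) and neither with an estimated correlation (adjusted p = 0.13 each), while their mean log2 fold changes were -0.03 and -0.02 against positive medians.

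Of 22025 genes 9913 passed here (3610 higher and 6303 lower in vehicle). The transcripts without a symbol moved mostly down (374 rose and 2374 fell), as did the snoRNA genes (1 rose and 162 fell, median -0.76), whereas protein-coding genes were split evenly (3104 and 3052). Of called genes 36.4% were higher and the median log2 fold change of all genes was -0.163, against 55.3% and 0.034 with quantile normalization. With the 75th percentile over all probes 67.2% were higher. Of the genes called, 6122 were also called after quantile normalization, and day 0 and vehicle lay on different slides. Of the 19 lists called, 8 lost their call in at least 1 alternative: adrenergic, neuronal, apoptosis, hypoxia, ribosomal, epithelial, G1/S and mitosis.

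**Figure D2:**
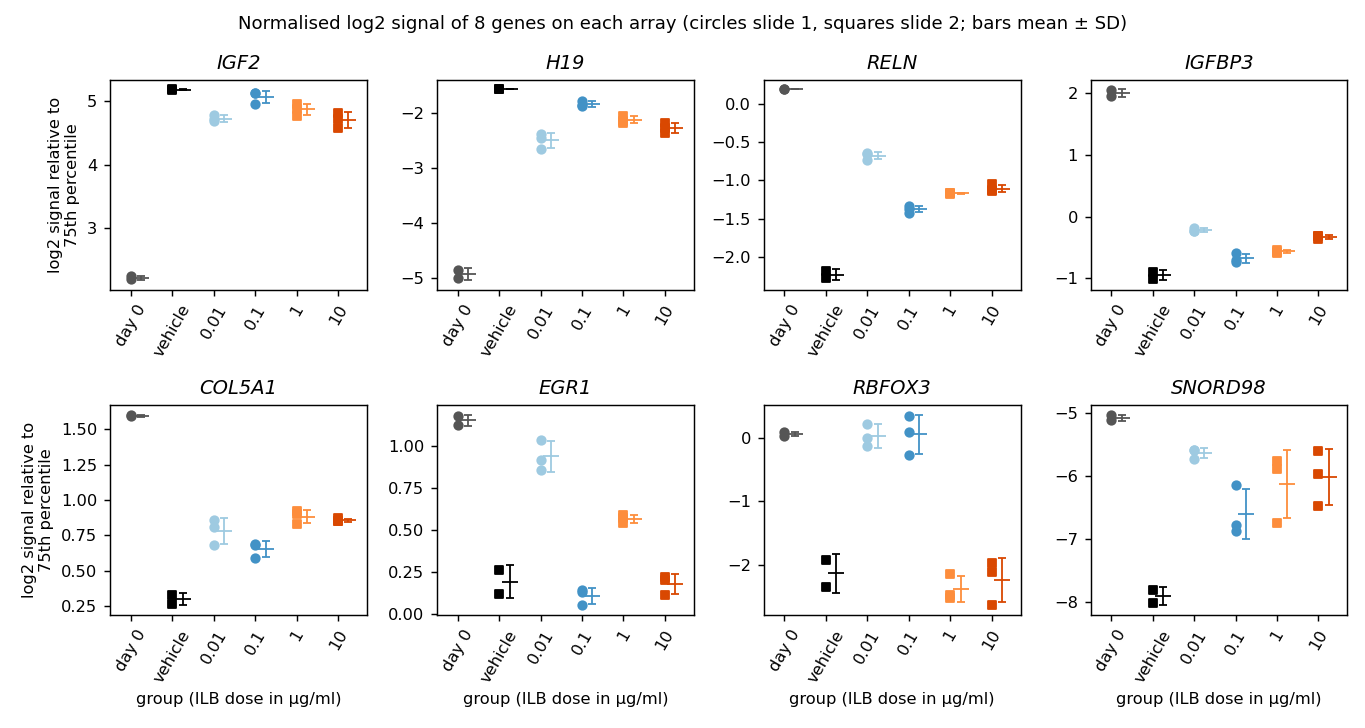
Normalized log2 signal (y axis, relative to the 75th percentile of the array) of 8 genes on each array, by group and ILB dose in µg/ml (x axis); circles are arrays of slide 1, squares arrays of slide 2, and bars the mean ± SD. Mean IGFBP3 signal was 2 at day 0, -0.95 in vehicle and -0.23 to -0.68 at the 4 doses, while the brightest probe of RBFOX3 stood near 0 on slide 1 (0.03 to 0.05) and near -2 on slide 2 (-2.14 to -2.38).

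The highest dose was compared with vehicle on the same slide (10 µg/ml, n = 3, against n = 2) for the effect of ILB on gene expression that the series addresses. Several genes that had risen over the 48 h without ILB were lower: H19 (-0.7 ± 0.08, 1.63-fold lower, adjusted p = 0.0017), SUSD2 (-0.57 ± 0.08), IGF2 (-0.47 ± 0.08, adjusted p = 0.0058), CBLN4 (-0.49 ± 0.09) and EGFLAM (-0.87 ± 0.22, adjusted p = 0.037). SELENOW, a small selenoprotein, fell by 0.55 on the log2 scale (SE 0.06, adjusted p = 0.00095). The collagen COL5A1 (0.56 ± 0.06, adjusted p = 0.0009) and the adhesive protein THBS2 (0.89 ± 0.18, adjusted p = 0.015) were higher. Among the largest rises were small nuclear and intronic RNAs: SNORD98, a snoRNA (at least 2.45-fold, adjusted p = 0.0057), SNORD17 (1.57 ± 0.21), SCARNA4 (1.29 ± 0.29), and the intronic transcripts KCNQ5-IT1 (1.64 ± 0.21), DAPK1-IT1 (1.36 ± 0.3) and ASAP1-IT1 (1.27 ± 0.2). So were the antisense RNA MARCHF11-AS1 (1.56 ± 0.24), the cell adhesion gene PCDHGB4 (1.38 ± 0.2), the ribosomal pseudogene RPS16P5 (1.32 ± 0.28) and the imprinted non-coding RNA KCNQ1OT1 (1.25 ± 0.19). The transporter SLC5A12 (-0.83 ± 0.22), the vesicle transport gene RAB27B (-0.58 ± 0.1), the small Cajal body RNA SCARNA13 (-0.51 ± 0.13) and the zinc finger gene ZNF408 (-0.5 ± 0.1) fell.

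Of 51 cytosolic ribosomal protein genes, 13 fell at 10 µg/ml against vehicle, none rose and 38 did not pass (21 fell adjusted over the list alone; camera adjusted p = 4.1e-14, and 0.15 with an estimated correlation). RPS3 stood at -0.37 ± 0.06, RPL18 at -0.23 ± 0.05 and RPL15 at -0.22 ± 0.04. Extracellular matrix had 7 rises, no fall and 22 members that did not pass (12 rose adjusted over the list alone; camera adjusted p = 7.5e-05, and 0.042 with an estimated correlation), with COL3A1 at 0.42 ± 0.1 and the laminin LAMA1 at 0.33 ± 0.06 besides COL5A1 and THBS2. Fibroblast markers had 3 rises, no fall and 7 that did not pass (4 rose adjusted over the list alone; camera adjusted p = 0.001), including DCN (0.41 ± 0.06) and the growth factor receptor PDGFRA (0.31 ± 0.04). Oxidative phosphorylation as a list was called down (camera adjusted p = 5.9e-09, and 0.042 with an estimated correlation), with 1 of 50 members past the threshold, SDHB (-0.19 ± 0.05), and none adjusted over the list alone. The proteasome list was called down (camera adjusted p = 1.6e-05, and 0.042 with an estimated correlation) with 1 of 31 members past the threshold, 1 adjusted over the list alone, PSMA5 (-0.21 ± 0.05). Camera also called glycolysis down (adjusted p = 0.0047), in which PGK1 (-0.2 ± 0.04) and ALDOC (-0.26 ± 0.06) fell and 14 members did not pass (2 fell adjusted over the list alone). G1/S and DNA replication (adjusted p = 0.004) and the cytosolic heat shock response (adjusted p = 0.015) were called down with none of 34 and 19 members past the threshold by either adjustment. With an estimated correlation the adjusted p was 0.15 for glycolysis, 0.15 for G1/S and 0.065 for heat shock.

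In all, 1422 genes passed at 10 µg/ml (1207 higher and 215 lower; 4464 at an unadjusted p under 0.05), of which 202 changed at least 2-fold in the fit. Among them 547 risen and 64 fallen transcripts had no symbol, and 37 of the 224 snoRNA genes rose and none fell (median 0.34). The count was 579 with quantile normalization, with which SNORD98, KCNQ5-IT1, MARCHF11-AS1, DAPK1-IT1, RPS16P5, EGFLAM, SLC5A12, RAB27B, SCARNA13, ZNF408, COL3A1, RPL15 and RPL18 no longer passed. Among the lists, the proteasome (adjusted p = 0.29), glycolysis (0.45), G1/S (0.34) and heat shock (0.53) were then not called. Of the 8 lists called at 10 µg/ml, extracellular matrix alone kept its call in all 29 settings. It was 349 on the arrays of slide 2 alone, and 0 by limma in a fit to these 5 arrays alone (4048 at an unadjusted p under 0.05). It was 333 without vehicle replicate 1, 794 without vehicle replicate 2 and 787 without ILB 10 replicate 3, and IGF2, CBLN4, KCNQ1OT1 and RPS3 were among the genes lost without vehicle replicate 1.

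At 1 µg/ml (n = 3, against vehicle, n = 2, on the same slide) SNORD17, a snoRNA, rose 3.94-fold (1.98 ± 0.21, adjusted p = 0.00052), and the intronic and antisense RNAs KCNQ5-IT1 (1.87 ± 0.21), ERC2-IT1 (1.73 ± 0.3) and MARCHF11-AS1 (1.69 ± 0.24) and the snoRNA SNORA15B-2 (1.68 ± 0.27) rose. COL5A1 rose by 0.59 ± 0.06 (adjusted p = 0.00035) and DCN by 0.46 ± 0.06 (adjusted p = 0.00082). The olfactory marker gene OMP (-1.48 ± 0.38), the chloride channel gene BEST3 (-0.94 ± 0.19), SLC5A12 (at least 1.12-fold), the non-coding RNA THORLNC (-0.88 ± 0.22) and EGFLAM (-0.82 ± 0.22) fell. The call of OMP was lost with normexp background correction (0.01) and so was that of BEST3 (0.14), where both values had the opposite sign.

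By gene list, oxidative phosphorylation was called down at 1 µg/ml (5 of 50 fell and none rose, 5 adjusted over the list alone; camera adjusted p = 1e-07, and 0.082 with an estimated correlation). SDHB stood at -0.32 ± 0.05 and ATP5F1B at -0.29 ± 0.05. The proteasome was called down too (3 of 31 fell, none rose, 5 fell adjusted over the list alone; camera adjusted p = 6.2e-07, and 0.04 with an estimated correlation). PSMA5 stood at -0.3 ± 0.05 and PSMC3 at -0.27 ± 0.06. Cytosolic ribosomal proteins had 6 falls and 45 members that did not pass (7 falls adjusted over the list alone; camera adjusted p = 0.00014, and 0.43 with an estimated correlation). RPL7 stood at -0.31 ± 0.05 and RPS3 at -0.37 ± 0.06. G1/S and DNA replication had 2 falls, among them TYMS (-0.17 ± 0.05), and 32 members that did not pass, with none past the threshold adjusted over the list alone (camera adjusted p = 9.4e-05, and 0.082 with an estimated correlation). Glycolysis had 3 falls and 13 that did not pass (4 falls and 1 rise adjusted over the list alone; camera adjusted p = 0.00077, and 0.09 with an estimated correlation), with PGK1 and ENO1 at -0.24 ± 0.04 and -0.24 ± 0.05. Camera called cholesterol biosynthesis and uptake down (adjusted p = 0.021, and 0.11 with an estimated correlation), with none of 24 members past the threshold by either adjustment. Extracellular matrix had 4 rises, no fall and 25 that did not pass (10 rose adjusted over the list alone; camera adjusted p = 0.0011), among them THBS2 (0.93 ± 0.18), COL3A1 (0.55 ± 0.1) and LAMA1 (0.32 ± 0.06). Fibroblast markers had 3 rises and 7 that did not pass (5 rose adjusted over the list alone; camera adjusted p = 0.0032), with PDGFRA at 0.22 ± 0.04; both lists had an adjusted p = 0.082 with an estimated correlation. Of the p53 targets 5 of 26 rose and none fell, 5 adjusted over the list alone (camera adjusted p = 0.026, and 0.11 with an estimated correlation). They included CCNG1 (0.4 ± 0.06, adjusted p = 0.0036), TP53I3 (0.25 ± 0.05), PLK3 (0.25 ± 0.05) and the stress cytokine GDF15 (0.3 ± 0.07).

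The count at 1 µg/ml was 2186 (1678 higher and 508 lower; 302 changed at least 2-fold). SnoRNA genes rose (81 of 224, none fell, median 0.45), and 686 of the risen genes had no symbol. By scaling, 76.8% of called genes were higher, against 58.2% with median scaling and 64.1% with the 75th percentile over all probes; 1214 passed with quantile normalization, without ERC2-IT1, MARCHF11-AS1, SNORA15B-2, COL3A1, GDF15 and the lists of glycolysis (adjusted p = 0.075) and cholesterol (adjusted p = 0.32). Of the 9 lists called at 1 µg/ml, the proteasome alone kept its call in all 29 settings. The count was 1170 on slide 2 alone, 736 with slide row as a block, 11 in a fit to these 5 arrays alone, 613 and 1197 without vehicle replicate 1 and 2, and 1219 without ILB 1 replicate 3.

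At 0.1 µg/ml (n = 3, against vehicle, n = 2, on another slide) COL5A1 rose by 0.36 ± 0.06 (adjusted p = 0.006), DCN by 0.29 ± 0.06 (adjusted p = 0.013), PDGFRA by 0.18 ± 0.04 and LAMA1 by 0.37 ± 0.06. The calcium-binding S100A5 rose by 2.23 ± 0.32 (adjusted p = 0.0039). Dim transcripts rose as well: the antisense RNA VCAN-AS1 (at least 4.52-fold), the small membrane protein SMIM24 (at least 5.41-fold), the dicarboxylate transporter SLC13A3 (at least 4.33-fold) and the hair keratin-associated KRTAP3-1 (at least 3.24-fold), none of which passed with quantile normalization. The focal adhesion protein TNS3 (-0.57 ± 0.11), FAM229A (-0.55 ± 0.1), the phosphatidylcholine synthesis gene PCYT1B (-0.53 ± 0.13, its other probe 0.48 ± 0.16), the ATP synthase gene ATP5MGL (-0.5 ± 0.11) and the transporter SLC35G2 (-0.5 ± 0.1) fell. S100A5, SLC13A3, KRTAP3-1, COL5A1, FAM229A, ATP5MGL and SLC35G2 also differed between high and low doses, which lay on different slides, and LAMA1 stood at -0.01 as the mean over its probes.

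Several lists of housekeeping and growth genes were called down at 0.1 µg/ml, with few members past the threshold. The proteasome had 2 falls and 29 members that did not pass (5 falls adjusted over the list alone; camera adjusted p = 1.4e-10). PSMA5 stood at -0.25 ± 0.05. Oxidative phosphorylation had 3 falls and 47 that did not pass, 3 adjusted over the list alone (camera adjusted p = 3.8e-09). COX4I1 stood at -0.27 ± 0.05 and ATP5F1B at -0.23 ± 0.05. Cholesterol biosynthesis and uptake had 2 falls and 22 that did not pass, 2 adjusted over the list alone (camera adjusted p = 5.4e-06), namely ACAT2 (-0.2 ± 0.05) and IDI1 (-0.2 ± 0.05). Glycolysis had 2 falls and 14 that did not pass, 2 adjusted over the list alone (camera adjusted p = 0.00017), namely PGK1 (-0.18 ± 0.04) and PGAM1 (-0.19 ± 0.05). Camera called G1/S and DNA replication (adjusted p = 4.8e-08) and mitosis (adjusted p = 0.00046) down with none of 34 members of either past the threshold by either adjustment. The cytosolic heat shock response (adjusted p = 0.015) had none of 19 over all genes and 2 falls adjusted over the list alone. In the amino acid and integrated stress response, 1 rose, 1 fell (MTHFD2, -0.24 ± 0.04) and 31 did not pass, 1 and 1 adjusted over the list alone (camera adjusted p = 0.0084). These 8 lists were also called with an estimated correlation. With quantile normalization only the proteasome and G1/S lists among them were called. The adjusted p was then 0.25 for oxidative phosphorylation, 0.05 for cholesterol, 0.54 for glycolysis, 0.94 for mitosis, 0.74 for heat shock and 0.75 for the stress response. Without ILB 0.1 replicate 2 the heat shock list (adjusted p = 0.057) and the stress response list (adjusted p = 0.05) were not called. A further 4 lists were called down. Apoptosis regulators had 1 fall, CYCS (-0.29 ± 0.06, its other probes 0.1 ± 0.04 and 0.13 ± 0.17), by either adjustment (adjusted p = 0.0082, and 0.09 with an estimated correlation). The hypoxia response had none of 25 past the threshold by either adjustment (adjusted p = 0.023, and 0.13 with an estimated correlation). Neuronal differentiation and synapse had 1 rise, 1 adjusted over the list alone, and 29 that did not pass (adjusted p = 0.03, 0.055 with an estimated correlation and 0.05 without ILB 0.1 replicate 2). Immediate early genes had 1 rise and 2 falls, DUSP1 (-0.24 ± 0.05) and MYC (-0.2 ± 0.04), with 1 and 3 adjusted over the list alone (adjusted p = 0.034, and 0.21 with an estimated correlation). The means of the heat shock, neuronal and immediate early lists were positive (0.05, 0.06 and 0.03) against negative medians. Extracellular matrix had 2 rises and 27 that did not pass (12 rose adjusted over the list alone; camera adjusted p = 0.0063, and 0.076 with an estimated correlation). Fibroblast markers had 2 rises and 8 that did not pass (4 rose adjusted over the list alone; camera adjusted p = 0.0088, and 0.055 with an estimated correlation).

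The count at 0.1 µg/ml was 1470 (1297 higher and 173 lower; 351 changed at least 2-fold), with 83 of 224 snoRNA genes risen and none fallen (median 0.49). ILB 0.1 replicate 2, the array with the high share of probes above background, took part in it: the count was 889 without that array, and 296 and 542 without vehicle replicate 1 and 2. With quantile normalization 325 passed and 69.2% of them were higher, against 88.2%, and the matrix list was called (adjusted p = 0.0006). Of the 14 lists called at 0.1 µg/ml, the proteasome and G1/S alone kept their call in all 29 settings. The 75th percentile over all probes gave 2319, of which 24.8% were higher, with PDGFRA at -0.03. A fit to these 5 arrays alone called 0 by limma (3314 at an unadjusted p under 0.05).

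At 0.01 µg/ml, the lowest dose (n = 3, against vehicle, n = 2, on another slide), more genes differed from vehicle than at the higher doses in the main processing. With no filter on dim probes 3476 did, fewer than the 9411 at 1 µg/ml. H19 (-0.93 ± 0.08, adjusted p = 3.2e-05), EGFLAM (-0.82 ± 0.22), the endopeptidase-like ECEL1 (-1.02 ± 0.18), ZNF408 (-0.94 ± 0.1) and the glucose-6-phosphatase G6PC3 (-0.79 ± 0.1) were lower. PDGFRA rose by 0.39 ± 0.04 (adjusted p = 6.6e-05), COL5A1 by 0.48 ± 0.06 (adjusted p = 0.00013), DCN by 0.49 ± 0.06 and COL3A1 by 0.69 ± 0.1. The dim transcripts CDKL4, a kinase (at least 3.33-fold, adjusted p = 6.6e-05), SNORD98 (at least 3.18-fold, adjusted p = 0.00036), KRTAP3-1 (at least 3.02-fold), NUGGC (at least 2.77-fold) and KRT73-AS1 (at least 2.12-fold) rose. NUGGC, KRT73-AS1, KRTAP3-1, ZNF408, EGFLAM and COL3A1 did not pass with quantile normalization.

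Lists of energy and protein quality genes were called down at 0.01 µg/ml against vehicle. Oxidative phosphorylation had 27 falls, no rise and 23 members that did not pass (31 falls adjusted over the list alone; camera adjusted p = 2.2e-15). ATP5F1B stood at -0.48 ± 0.05 (adjusted p = 0.00011) and SDHB at -0.41 ± 0.05. The proteasome had 19 falls and 12 that did not pass (24 falls adjusted over the list alone; camera adjusted p = 9.8e-13). PSMC3 stood at -0.43 ± 0.06 and PSMB5 at -0.38 ± 0.05. Of 16 glycolysis genes 12 fell, 12 adjusted over the list alone (camera adjusted p = 1.5e-08), among them ALDOC (-0.46 ± 0.06), ENO1 (-0.39 ± 0.05) and PGK1 (-0.38 ± 0.04). In cholesterol biosynthesis and uptake there were 9 falls and 15 that did not pass (13 falls adjusted over the list alone; camera adjusted p = 2e-07). TM7SF2 stood at -0.37 ± 0.06 and ACAT2 at -0.32 ± 0.05. G1/S and DNA replication had 1 rise, 15 falls and 18 that did not pass (1 and 16 adjusted over the list alone; camera adjusted p = 7.7e-06). GINS2 stood at -0.3 ± 0.05. The cytosolic heat shock response had 7 falls and 12 that did not pass (8 falls adjusted over the list alone; camera adjusted p = 0.0001). The co-chaperone AHSA1 stood at -0.51 ± 0.08. The amino acid and integrated stress response had 4 rises, 9 falls and 20 that did not pass (4 and 13 adjusted over the list alone; camera adjusted p = 0.00012). DDIT4 stood at -0.4 ± 0.06 and MTHFD2 at -0.34 ± 0.04. These 7 were also called with an estimated correlation.

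A further 6 lists were called down at 0.01 µg/ml without such a call. Mitosis had 4 rises, 9 falls and 21 that did not pass (4 and 10 adjusted over the list alone; camera adjusted p = 0.0035, and 0.068 with an estimated correlation). CDCA8 stood at -0.26 ± 0.05. Lysosome and autophagy had 9 falls, no rise and 32 that did not pass (7 falls adjusted over the list alone; camera adjusted p = 0.0067, and 0.068 with an estimated correlation). The proton pump subunit ATP6V0D1 stood at -0.42 ± 0.06 and the calcium channel MCOLN1 at -0.48 ± 0.09. Cytosolic ribosomal proteins had 4 rises, 10 falls and 37 that did not pass, 4 and 10 adjusted over the list alone (camera adjusted p = 0.02, and 0.59 with an estimated correlation). RPS3 stood at -0.49 ± 0.06. Apoptosis regulators had 4 rises, 7 falls and 22 that did not pass (4 and 8 adjusted over the list alone; camera adjusted p = 0.023, and 0.14 with an estimated correlation). CYCS stood at -0.36 ± 0.06 and its other probes at -0.03 ± 0.04 and 0.02 ± 0.17. Neuronal differentiation and synapse had 2 rises, 6 falls and 22 that did not pass, 2 and 6 adjusted over the list alone (camera adjusted p = 0.042, and 0.07 with an estimated correlation). STMN3 stood at -0.55 ± 0.08. Fatty acid synthesis and desaturation had 1 rise, 2 falls (ELOVL1 at -0.54 ± 0.09 and FADS2 at -0.2 ± 0.06) and 12 that did not pass, 1 and 2 adjusted over the list alone (camera adjusted p = 0.046, and 0.088 with an estimated correlation). Upwards, fibroblast markers had 3 rises and 7 that did not pass, 3 adjusted over the list alone (camera adjusted p = 0.023, and 0.088 with an estimated correlation). Extracellular matrix had 10 rises, 1 fall and 18 that did not pass (13 and 1 adjusted over the list alone; camera adjusted p = 0.044, and 0.18 with an estimated correlation). LAMC1 stood at 0.34 ± 0.05.

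The count at 0.01 µg/ml was 6335 (4282 higher and 2053 lower; 1219 changed at least 2-fold). Of the snoRNA genes 128 of 224 rose and none fell (median 0.59). Transcripts without a symbol had 1749 rises and 208 falls, against 1911 and 1783 for protein-coding genes. With quantile normalization 4084 passed and 50.2% of them were higher, against 67.6%, and with the 75th percentile over all probes 31.5% were higher. The count was 3242 without vehicle replicate 1. Of the 15 lists called, the 7 that were also called with an estimated correlation kept their call in all 29 settings.

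**Figure D3:**
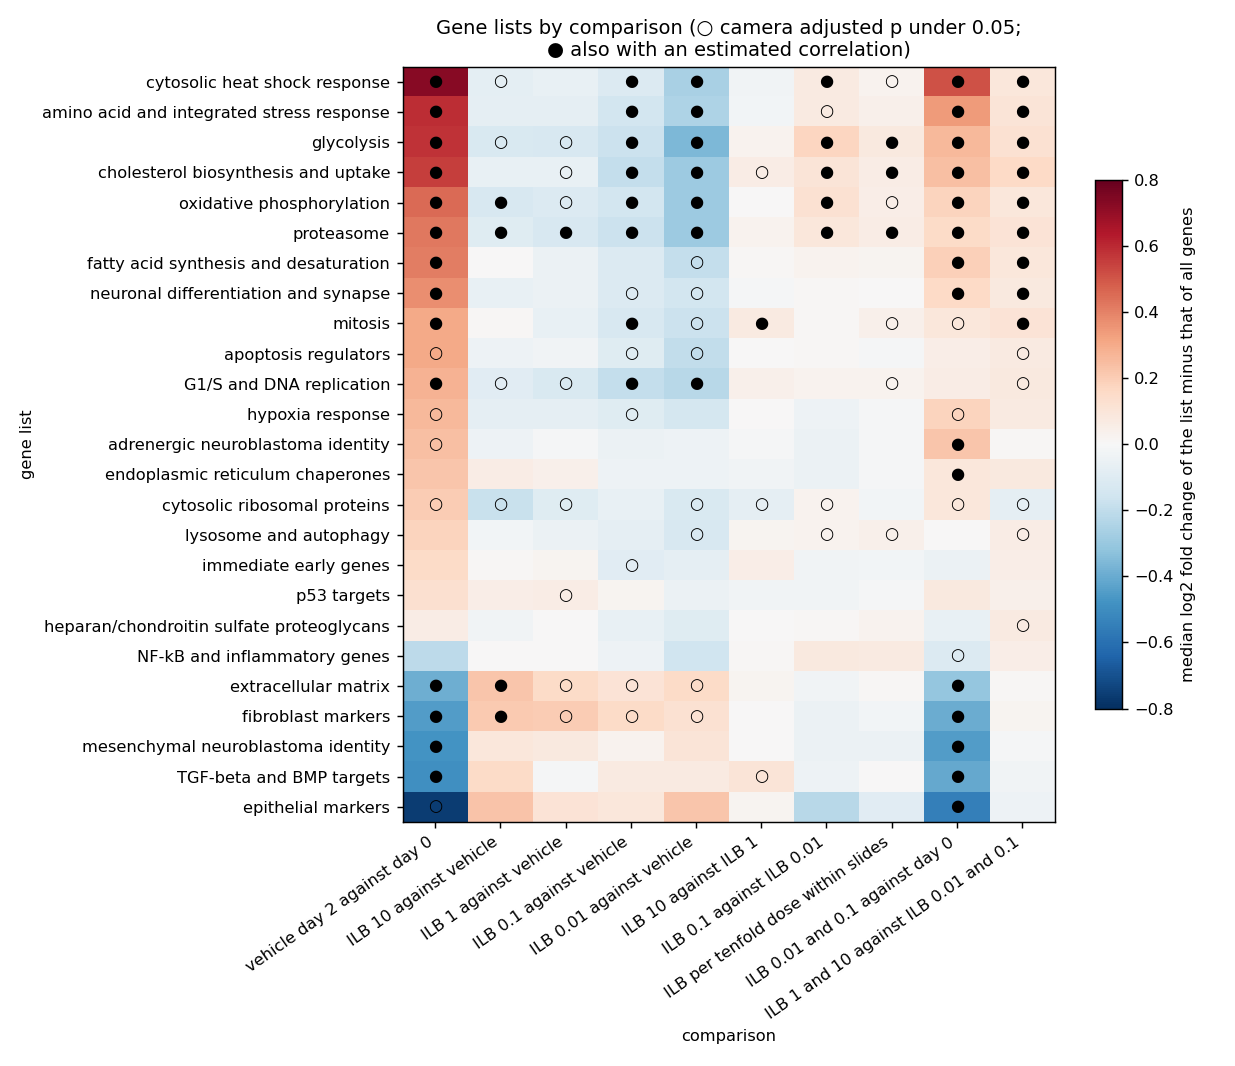
Median log2 fold change of each gene list minus that of all genes (colour), by comparison (x axis) and gene list (y axis), for lists called in at least 1 comparison; open circles mark lists with a camera adjusted p under 0.05 and filled circles those also called with an estimated correlation. Vehicle against day 0 has the strongest colours. The 4 ILB columns against vehicle run mostly opposite, in part because they share the vehicle arrays.

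The 2 high doses were compared with each other on slide 2 (10 µg/ml against 1 µg/ml, n = 3 each), for the dose dependence of the response. SELENOW fell by 0.55 on the log2 scale (SE 0.05, 1.46-fold lower, adjusted p = 0.0052), and it was the single gene that passed (1551 genes at an unadjusted p under 0.05; 2 passed with quantile normalization). Camera called 4 lists of which no member passed over all genes. Mitosis was called up (median 0.07, adjusted p = 5.4e-07, and 0.027 with an estimated correlation), with none past the threshold over the list alone. TGF-beta and BMP targets were called up (median 0.1, adjusted p = 0.016, and 0.51 with an estimated correlation), with 3 of 21 risen adjusted over the list alone. The list of cholesterol biosynthesis and uptake was called up (median 0.06, adjusted p = 0.046, and 0.39 with an estimated correlation). Cytosolic ribosomal proteins were called down (median -0.07, adjusted p = 9.2e-08, and 0.51 with an estimated correlation), and their median was 0.01 with quantile normalization. The call of SELENOW was lost without ILB 1 replicate 1, with slide row as a block, with the 75th percentile over all probes and on slide 2 alone, where limma called 0 genes (1548 at an unadjusted p under 0.05). There were 2 genes without ILB 1 replicate 2 or replicate 3. Of the 4 lists, mitosis alone kept its call in all 29 settings.

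On slide 1, 0.1 µg/ml was compared with 0.01 µg/ml (n = 3 each). Several metabolic genes were higher at 0.1 µg/ml: the glycolytic enzymes ENO1 (0.28 ± 0.04, adjusted p = 0.0028), PFKL (0.43 ± 0.07), ALDOC (0.29 ± 0.05) and PGK1 (0.2 ± 0.04). So were the proteasome subunits PSMB5 (0.3 ± 0.04, adjusted p = 0.0026) and PSMB6 (0.32 ± 0.06), and GDF15, a stress cytokine (0.38 ± 0.07, adjusted p = 0.005). CABP7, a calcium-binding protein, rose by 1.4 ± 0.23 (adjusted p = 0.0039), the transcription factor CSRNP1 by 2.49 ± 0.73 (adjusted p = 0.047), the adaptor SH2D4B by 2.42 ± 0.68, the cell surface protein LYPD3 by 1.36 ± 0.38 and the syntaxin STX19 by 1.12 ± 0.31. CDKL4 (at least 1.83-fold), RPS16P5 (at least 2.36-fold), PNISR-AS1 (at least 1.11-fold), ZSCAN23 (-1.21 ± 0.26) and MARCHF11-AS1 (-1.17 ± 0.22) fell.

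All 8 lists called between these doses were called up, and glycolysis and oxidative phosphorylation alone kept their call in all 29 settings. With no filter on dim probes the adjusted p was 0.13 for the proteasome, 0.26 for heat shock, 0.38 for cholesterol, 0.97 for ribosomal proteins and 0.76 each for the stress response and lysosome lists. Oxidative phosphorylation had 9 rises and 41 members that did not pass (23 rose adjusted over the list alone; camera adjusted p = 1.8e-09). CYC1 stood at 0.31 ± 0.06. Glycolysis had 12 rises and 4 that did not pass (13 adjusted over the list alone; camera adjusted p = 4.8e-07). The proteasome had 5 rises and 26 that did not pass (6 adjusted over the list alone; camera adjusted p = 1.9e-05). The cytosolic heat shock response had 4 rises and 15 that did not pass (6 adjusted over the list alone; camera adjusted p = 0.0016). The co-chaperone FKBP4 stood at 0.33 ± 0.09. Cholesterol biosynthesis and uptake had 4 rises and 20 that did not pass, 4 adjusted over the list alone (camera adjusted p = 0.0032). MVD stood at 0.35 ± 0.07. Ribosomal proteins had 6 rises and 45 that did not pass, 6 adjusted over the list alone (camera adjusted p = 0.0032, and 0.66 with an estimated correlation). RPS3 stood at 0.29 ± 0.06. The amino acid and integrated stress response had 5 rises, 2 falls and 26 that did not pass (11 and 3 adjusted over the list alone; camera adjusted p = 0.0092, and 0.053 with an estimated correlation). PCK2 stood at 0.27 ± 0.06. Lysosome and autophagy had 4 rises and 37 that did not pass, 4 adjusted over the list alone (camera adjusted p = 0.011, and 0.11 with an estimated correlation). MCOLN1 stood at 0.4 ± 0.08 and the protease CTSD at 0.3 ± 0.07. In this comparison 2683 genes passed (1030 higher and 1653 lower; 168 at least 2-fold), 1405 with slide row as a block and 1516 on slide 1 alone. With the 75th percentile over all probes, 1186 passed and 19.1% of them were higher, against 38.4%. The count was 1323, 1427 and 1370 without ILB 0.01 replicate 1, ILB 0.01 replicate 3 and ILB 0.1 replicate 3, and CSRNP1, SH2D4B, LYPD3 and STX19 did not pass without ILB 0.1 replicate 2.

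The mean change for a 10-fold dose step within slides joined the last 2 comparisons (12 arrays). EGR1, an immediate early transcription factor, fell by 0.61 on the log2 scale per 10-fold step (SE 0.04, adjusted p = 0.00014), and had mean signals of 0.94 at 0.01, 0.11 at 0.1, 0.57 at 1 and 0.18 at 10 µg/ml, against 1.15 at day 0 and 0.19 in vehicle. The exchange factor ARHGEF28 (-0.42 ± 0.06, its other probe 0.24 ± 0.15), TFAP4 (-0.56 ± 0.09), LRRC39 (-0.49 ± 0.09) and SNORD45B (-0.43 ± 0.11) fell. The lipoprotein receptor family member LRP10 (0.4 ± 0.04, adjusted p = 0.0016), ROGDI (0.36 ± 0.04), FAM171A2 (0.36 ± 0.08) and the hyaluronidase HYAL1 (0.38 ± 0.09) rose. Glycolysis had 4 rises and 12 members that did not pass (12 rose adjusted over the list alone; camera adjusted p = 2.6e-07). PFKL stood at 0.26 ± 0.05 and ENO1 at 0.19 ± 0.03. The proteasome had 3 rises and 28 that did not pass, 3 adjusted over the list alone (camera adjusted p = 3.5e-06). PSMC3 stood at 0.19 ± 0.04. Cholesterol biosynthesis and uptake had 2 rises and 22 that did not pass (8 adjusted over the list alone; camera adjusted p = 0.00017). MVD stood at 0.2 ± 0.05. Oxidative phosphorylation had 4 rises and 46 that did not pass (9 adjusted over the list alone; camera adjusted p = 2.6e-07, and 0.064 with an estimated correlation). ATP5F1B stood at 0.2 ± 0.03. Mitosis had 1 rise, CDCA8 (0.13 ± 0.03), and 33 that did not pass (4 adjusted over the list alone; camera adjusted p = 0.0021, and 0.064 with an estimated correlation). Lysosome and autophagy had 2 rises, MCOLN1 (0.34 ± 0.06) and CLN3 (0.36 ± 0.07), and 39 that did not pass, 2 adjusted over the list alone (camera adjusted p = 0.0022, and 0.064 with an estimated correlation). Camera called the heat shock list up with no member past the threshold by either adjustment (adjusted p = 0.036, and 0.073 with an estimated correlation). It called the G1/S list up with none over all genes and 1 rise and 1 fall adjusted over the list alone (adjusted p = 0.041, and 0.35 with an estimated correlation), and the mean of that list was 0. Of these 8 lists, glycolysis, the proteasome and cholesterol kept their call in all 29 settings. In all 1013 genes passed (313 higher and 700 lower; 10 at least 2-fold), 223 with the 75th percentile over all probes and 35 with slide row as a block. In the last, EGR1, LRP10 and ROGDI still passed and the other genes named here did not. Without 1 array the count was 459, 545 and 522 for ILB 0.01 replicate 1, 2 and 3, 499 for ILB 0.1 replicate 3, 394 for ILB 1 replicate 3, and 525 and 445 for ILB 10 replicate 1 and 2.

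The low doses together (n = 6) were compared with day 0 (n = 2), both on slide 1, for the change over 48 h in the presence of ILB. H19 rose 6.79-fold (2.76 ± 0.07, adjusted p = 1.7e-09), IGF2 rose 6.36-fold (2.67 ± 0.07), EGFLAM by 2.81 ± 0.19, SUSD2 by 2.53 ± 0.07 and HS3ST2 by 2.21 ± 0.09. IGFBP3, a secreted protein that binds insulin-like growth factors, fell 5.49-fold (-2.46 ± 0.05, adjusted p = 2.7e-10), with BMPER (-3.15 ± 0.41), EDN1 (-2.6 ± 0.17), ADRA2A (-2.53 ± 0.42) and COL6A6 (at least 3.39-fold). Vehicle had moved the same way against day 0, and the 9 genes besides IGFBP3 were among the largest changes there.

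Heat shock genes had 16 rises, no fall and 3 members that did not pass, 16 adjusted over the list alone (camera adjusted p = 2.4e-13). HSPA1B stood at 0.98 ± 0.04 and HSPA4L at 1.07 ± 0.08. Oxidative phosphorylation had 23 rises and 27 that did not pass (27 adjusted over the list alone; camera adjusted p = 5e-10). The amino acid and integrated stress response had 18 rises, 1 fall and 14 that did not pass (21 and 2 adjusted over the list alone; camera adjusted p = 2.6e-09). CHAC1 stood at 0.96 ± 0.07. Cholesterol biosynthesis and uptake had 14 rises and 10 that did not pass, 14 adjusted over the list alone (camera adjusted p = 3e-08). The proteasome had 14 rises and 17 that did not pass, 15 adjusted over the list alone (camera adjusted p = 1.2e-06). Glycolysis had 10 rises, 2 falls and 4 that did not pass, 11 and 2 adjusted over the list alone (camera adjusted p = 2.1e-05). Fatty acid synthesis had 8 rises, 1 fall and 6 that did not pass, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00052). These 7 lists were also called with an estimated correlation. Adrenergic neuroblastoma identity had 11 rises, 3 falls and 8 that did not pass, 11 and 3 adjusted over the list alone (camera adjusted p = 0.00038, and 0.037 with an estimated correlation). CHGB stood at 1.43 ± 0.05, DBH at 1.1 ± 0.08 and the transcription factor HAND1 at 0.68 ± 0.06. Endoplasmic reticulum chaperones and the unfolded protein response had 9 rises, 3 falls and 11 that did not pass, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0059, and 0.026 with an estimated correlation). The transcription factor XBP1 stood at 0.51 ± 0.04 and the chaperone HSPA5 at 0.43 ± 0.04. Neuronal differentiation and synapse had 12 rises, 5 falls and 13 that did not pass, 12 and 5 adjusted over the list alone (camera adjusted p = 0.034, and 0.048 with an estimated correlation). INA stood at 0.43 ± 0.04.

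Downwards, TGF-beta and BMP targets had 1 rise, 13 falls and 7 that did not pass, 1 and 13 adjusted over the list alone (camera adjusted p = 9.9e-08). SMAD6 stood at -1.62 ± 0.06 and ID1 at -1.09 ± 0.05. Extracellular matrix had 3 rises, 13 falls and 13 that did not pass (3 and 15 adjusted over the list alone; camera adjusted p = 8.4e-05). COL5A1 stood at -0.88 ± 0.05. Mesenchymal neuroblastoma identity had 10 falls and 7 that did not pass (11 adjusted over the list alone; camera adjusted p = 0.00012). SNAI2, a transcription factor of mesenchymal cells, stood at -1.24 ± 0.15. Fibroblast markers had 1 rise, 6 falls and 3 that did not pass (7 falls adjusted over the list alone; camera adjusted p = 0.0012). Of 6 epithelial markers 5 fell, 5 adjusted over the list alone (camera adjusted p = 0.0016). These 5 falling lists were also called with an estimated correlation. Of the NF-kB and inflammatory genes 4 of 14 fell and none rose (5 fell adjusted over the list alone; camera adjusted p = 0.043, and 0.17 with an estimated correlation). The chemokine CCL2 stood at -1.41 ± 0.1 (adjusted p = 2.2e-06) and IL32 at -1.55 ± 0.25. Ribosomal proteins had 11 rises and 40 that did not pass, 9 adjusted over the list alone (camera adjusted p = 0.0025, and 0.46 with an estimated correlation). Mitosis had 6 rises, 1 fall and 27 that did not pass, 6 and 1 adjusted over the list alone (camera adjusted p = 0.032, and 0.13 with an estimated correlation). The hypoxia response had 11 rises, 5 falls and 9 that did not pass, 14 and 5 adjusted over the list alone (camera adjusted p = 0.037, and 0.17 with an estimated correlation). Its mean was -0.03 against a positive median. Of the 19 lists called, 7 lost their call in at least 1 alternative: ribosomal, unfolded protein response, epithelial, hypoxia, mitosis, neuronal and NF-kB. In all 5857 genes passed (2546 higher and 3311 lower; 519 at least 2-fold), 4788 on slide 1 alone, with 1 snoRNA gene risen and 55 fallen (median -0.24). The count was 3060 and 3116 without day 0 replicate 1 and 2, and 43.5% of called genes were higher, against 62.5% with median scaling.

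The high doses together (n = 6, slide 2) were compared with the low doses (n = 6, slide 1), a contrast in which dose and slide cannot be told apart. RBFOX3, a neuronal splicing factor, was 5.11-fold lower at the high doses by its brightest probe (-2.35 ± 0.14, adjusted p = 1.1e-05). Its other probe did not pass (0.25 ± 0.35, adjusted p = 0.7). S100A5 was 5.96-fold lower (-2.57 ± 0.2) and the cytokine IL16 was lower (-2.14 ± 0.18). For RBFOX3 the vehicle arrays, on slide 2, stood at -2.14 and the day 0 arrays, on slide 1, at 0.05, although none of them held ILB. SLC13A3 (at least 1.66-fold) and ARHGEF3-AS1 (at least 1.72-fold) were lower, and the annexin partner S100A10 (0.61 ± 0.08), ATP5MGL (0.46 ± 0.07), SCRG1 (0.46 ± 0.08), FAM229A (0.45 ± 0.06) and the glutamate receptor GRM8 (0.39 ± 0.07) were higher.

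Cholesterol biosynthesis and uptake had 3 rises and 21 members that did not pass (11 rose adjusted over the list alone; camera adjusted p = 6.3e-11). INSIG1 stood at 0.3 ± 0.06. Mitosis had 6 rises and 28 that did not pass (7 adjusted over the list alone; camera adjusted p = 1.4e-09). CCNB1 stood at 0.17 ± 0.02 (adjusted p = 0.0023) and CENPE at 0.16 ± 0.03. Ribosomal proteins had 2 falls, RPL23 (-0.18 ± 0.03) and RPL5 (-0.14 ± 0.03), and 49 that did not pass, with 33 falls adjusted over the list alone (camera adjusted p = 1.4e-09, and 0.18 with an estimated correlation). The proteasome was called up with 1 rise, PSMA3 (0.12 ± 0.03), and 1 adjusted over the list alone (camera adjusted p = 7.7e-10). Glycolysis had 1 rise, PGAM1 (0.13 ± 0.03), and 3 adjusted over the list alone (camera adjusted p = 8.2e-08). Oxidative phosphorylation was called up with none of 50 past the threshold by either adjustment (camera adjusted p = 2.4e-07). In the amino acid and integrated stress response 2 rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 7.7e-05). Fatty acid synthesis had 2 rises, SREBF1 and GPAM (0.13 ± 0.03 each, the other probe of SREBF1 at -0.1 ± 0.08), and 2 adjusted over the list alone (camera adjusted p = 0.00088). Heat shock genes had 2 rises, HSPA4 (0.17 ± 0.03, its other probe -0.14 ± 0.04) and HSPA1A (0.1 ± 0.02), and 1 fall, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.0012). The neuronal list was called up (camera adjusted p = 0.022) although 2 members fell, with 5 rises and 2 falls adjusted over the list alone. Apart from the ribosomal list, these were also called with an estimated correlation, but the fatty acid and neuronal lists were not called with quantile normalization (adjusted p = 0.083 and 0.17). With no filter on dim probes the stress response and heat shock lists (adjusted p = 0.6 each) and oxidative phosphorylation (adjusted p = 0.18) were not called. Of the 14 lists called, cholesterol, mitosis, the proteasome and glycolysis alone kept their call in all 29 settings. Camera called 4 more lists up. G1/S had 1 rise, GINS1 (0.13 ± 0.03), and none adjusted over the list alone (adjusted p = 0.0002, and 0.05 with an estimated correlation). Of the apoptosis regulators none of 33 passed by either adjustment (adjusted p = 0.0041, and 0.078 with an estimated correlation). Of the lysosome list none of 41 did (adjusted p = 0.032, and 0.11 with an estimated correlation). Heparan and chondroitin sulfate proteoglycans and their synthesis had 1 fall by either adjustment and 38 that did not pass (adjusted p = 0.036, and 0.05 with an estimated correlation). The means of the stress response, heat shock, neuronal and proteoglycan lists were negative (-0.02, -0.03, -0.08 and -0.01) against positive medians.

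Between high and low doses 1144 genes passed (214 higher and 930 lower; 270 at least 2-fold). With no filter on dim probes the balance turned, with 3527 higher and 1050 lower. SnoRNA genes had 7 falls and no rise (median -0.13). With quantile normalization 417 passed and 38.1% of them were higher, against 18.7%, and SCRG1, ARHGEF3-AS1, MVK (0.15 ± 0.03 here), RPL23 and RPL5 were not among them. The count was 703 with slide row as a block, and 720, 621 and 757 without ILB 0.01 replicate 1, ILB 0.01 replicate 2 and ILB 1 replicate 1.

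Across comparisons, genes called at both 1 and 10 µg/ml against vehicle moved the same way: 1050 rose in both (92 by chance), 133 fell in both (5 by chance) and none went opposite ways. As both use the same 2 vehicle arrays, such overlap arises in part by construction, and genes are not independent replicates. The correlation across genes was 0.76 (0.6 in simulated data without group differences) and the covariance 0.1085 (0.0584). For 0.1 µg/ml with 1 and 10 µg/ml the correlations were 0.54 and 0.55 (0.6 simulated) and the covariances 0.1003 and 0.0988 (0.0583 and 0.0584). Simulated arrays shared 1 spread per gene. Replicates differed by an SD of 0.342 in vehicle and 0.813 for ILB 0.1 replicates 2 and 3, so simulated values are approximate. Changes at 10 µg/ml also ran against the change from day 0 to vehicle: of genes called in both, 1183 fell over the 48 h and were higher with ILB (345.4 by chance), 186 rose and were lower with ILB (35.2 by chance). Another 2 and 4 moved up or down in both. The correlation was -0.71 (-0.55 simulated) and the covariance -0.1857 (-0.0581). For the reelin gene RELN, a secreted guide of neuronal migration, the mean signal was 0.19 at day 0, -2.23 in vehicle and -0.68, -1.38, -1.17 and -1.11 from the lowest to the highest dose.

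**Figure D4:**
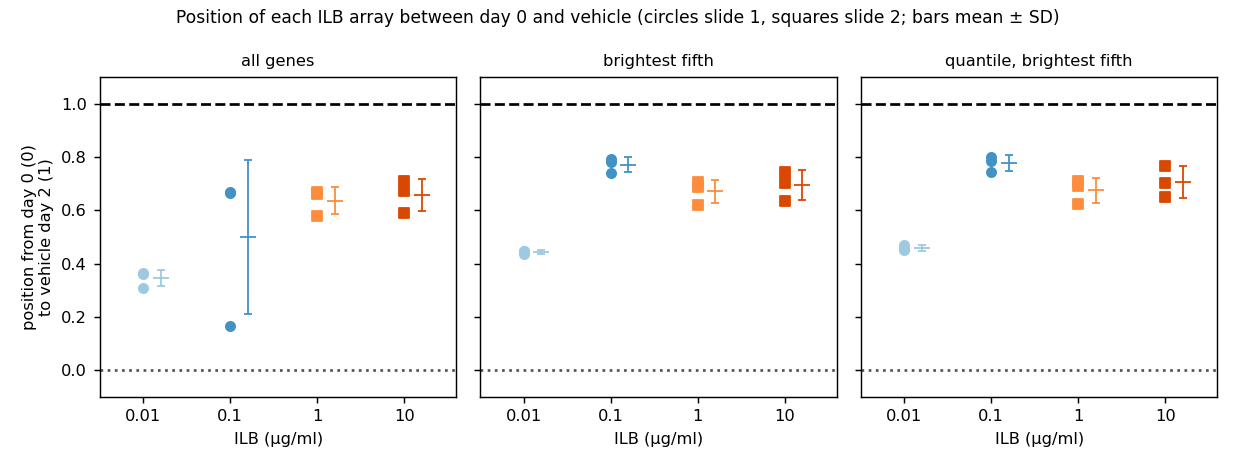
Position of each ILB array (y axis) between the mean of day 0 (dotted line, 0) and the mean of vehicle at day 2 (dashed line, 1), by ILB dose in µg/ml (x axis), over all genes, the 4346 brightest genes, and these after quantile normalization; circles are slide 1, squares slide 2, bars the mean ± SD. All arrays lay between both lines, with means over all genes of 0.34, 0.5, 0.64 and 0.66 from the lowest to the highest dose.

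Over all genes, the ILB arrays lay between day 0 (set to 0) and vehicle (set to 1): at 0.34 ± 0.03 (SD, n = 3) for 0.01, 0.5 ± 0.29 for 0.1, 0.64 ± 0.05 for 1 and 0.66 ± 0.06 for 10 µg/ml, and ILB 0.1 replicate 2 stood at 0.17. Over the 4346 brightest genes, on which that array lay with its replicates, the order of the doses differed: 0.44 ± 0.01, 0.77 ± 0.03, 0.67 ± 0.05 and 0.69 ± 0.06. In none of the 10 comparisons did camera call the interferon-stimulated genes, the NRF2 oxidative stress response, the heparin-binding growth factors, or the Schwann and glial cell and leukocyte markers, of which 19, 21, 29, 8 and 5 members were tested.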

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

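The tests of the axis from other arrays, of the order on the slides, of the step between slides and of the small RNA genes were chosen after their results had been seen; the intensity test and the counts over other splits of the arrays were planned before.

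At the same 10-fold step in dose, 2683 genes passed between 0.1 and 0.01 µg/ml on slide 1 and 1 gene (SELENOW) passed between 10 and 1 µg/ml on slide 2, and the difference between these effects was not itself tested. In the other 9 splits of the 6 arrays of each pair into groups of 3, at most 0 genes passed for the first pair and at most 1 for the second; 1 of 10 and 2 of 10 splits, the real split included, gave as many genes, and 10 splits are too few for a share under 0.05. For the mean 10-fold step within slides, 3 of 100 splits, the real one included, reached the real 1013 genes (highest other 1564). Both higher splits exchanged all 6 arrays between the low doses, which keeps the low-dose difference with its sign turned. They mixed the high-dose arrays (4 and 2 of 6 exchanged). Chance is thus not excluded for a step shared by both slides. Splits that exchanged the same arrays of slide 1 gave 36 to 1564 genes, so the count depended on both slides. With slide row as a block the count was 1405 for 0.1 against 0.01 µg/ml and 35 for the mean step.

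Between high and low doses 1144 genes passed, S100A5 and IL16 among them. In 1 of 100 splits of the 12 arrays, the real one, as many did (highest other 3). All other splits mixed arrays of both slides, whereas the real one follows the slides. The count thus argues against a random division of these arrays, but it cannot exclude chance differences between slides or cultures. A threshold of ILB dose between 0.1 and 1 µg/ml was argued against by the vehicle arrays, which had no ILB and whose median step from the low doses was 1.02 of that from low to high dose. A difference between the slides may account for the pattern: vehicle lay with the high doses and day 0 with the low doses, the larger of the 2 median offsets being 0.12 of the step. For the 270 genes that changed at least 2-fold, the offsets were -0.07 and -0.01 of the step. A biological difference between the cultures of both slides, such as another batch of cells, stays open and untested.

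Over all genes the ILB arrays of each dose lay between day 0 and vehicle, as for RELN, IGFBP3 and COL5A1; over the 4346 dimmest genes ILB 0.1 replicate 2 lay outside, at -0.13. These positions were all taken on an axis from other arrays than its ends, and no second axis was computed. On it the 3 ILB 10 arrays lay at 0.66 ± 0.06 (SD) rather than at 1. That argued against the use of the same arrays for the axis and its ends as the cause. Intensity-dependent scaling was argued against by the 4346 brightest genes after quantile normalization, on which they lay at 0.71 ± 0.06. An even drift along the slide was argued against too. The step per place from ILB 1 to ILB 10 was 0.05 of that from ILB 10 to vehicle. Vehicle held the last 2 places, so an effect of place stays open. So do an effect of ILB and a difference of the only 2 vehicle cultures, and no test separated these. For the low doses the slide cannot be told apart from the group.

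Genes of small nucleolar RNAs were lowest in vehicle: 37 of 224 rose at 10 µg/ml and 128 at 0.01 µg/ml, none fell, and the median log2 fold change at 10 µg/ml was 0.34. Dim probes moving together were argued against by 1000 sets of protein-coding genes of the same signal, whose medians ranged from -0.02 to 0.09. A differing share of unspliced nuclear RNA in the extracts may account for it: 26 transcripts named as intronic, KCNQ5-IT1 and DAPK1-IT1 among them, had a median of 0.73 in the same comparison (matched sets -0.13 to 0.3) and of -1.7 in vehicle against day 0. Whether such a share reflects the cells or the extraction was not tested, and with quantile normalization the medians at 10 µg/ml were 0.19 and 0.42. At 0.1 µg/ml the intronic transcripts went against this account with quantile normalization, where their median was -0.12 (0.61 without) and that of the small nucleolar RNA genes 0.16 (0.49 without).

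On ILB 0.1 replicate 2 the median log2 signal of the spike-in control spots was 5.98, against 2.82 to 3.85 on the other arrays and 2.82 to 3.29 on the arrays without ILB.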

How the results depend on the processing

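The alternatives chosen after the data were seen are named with the methods. Signal over background limited the dim transcripts, and the number of arrays, 2 in day 0 and vehicle, limited all comparisons. Over the alternatives other than leaving out arrays, 115 counts stayed within 1.5 times the main count and 56 did not; 1302 list tests kept their call and direction, 230 lost the call and 2 turned; 5872 values of named genes kept both, 1232 lost the call and 9 turned. With replicate number as a block 41 of 436 named-gene calls and 1 of 118 list calls were lost. The counts were 9542, 1053, 1665, 1089, 5686, 1, 2250, 771, 5316 and 978 in the above order of comparisons. Replicate numbers did not pair the samples, since 7 of 16 arrays were closest to the array of their own number in another group and deviations of arrays of 1 number correlated across genes at -0.08 to 0.27.

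With normexp background correction the count was 5986 for 1 µg/ml and 3813 for 0.1 µg/ml against vehicle, 2 for 10 against 1 µg/ml and 653 for high against low doses. Quantile normalization gave 579, 1214, 325 and 4084 from the highest to the lowest dose against vehicle, 2 for 10 against 1 µg/ml and 417 for high against low doses; without ILB 0.1 replicate 2 as well it gave 282 for 0.1 µg/ml, 11 for 10 against 1 µg/ml and 690 for high against low doses. The 75th percentile over all probes gave 395, 971 and 2319 for 10, 1 and 0.1 µg/ml, 0 for 10 against 1 µg/ml (1044 at an unadjusted p under 0.05), 1186 for 0.1 against 0.01 µg/ml and 223 per 10-fold step. With no filter on dim probes the counts were 637, 9411, 786 and 3476 from the highest to the lowest dose, 0 for 10 against 1 µg/ml (2952 at an unadjusted p under 0.05), 843 for 0.1 against 0.01 µg/ml, 19 per 10-fold step, 3167 for low doses against day 0 and 4577 for high against low doses. The eBayes trend gave 2 for 10 against 1 µg/ml. With slide row as a block the counts were 736 for 1 µg/ml, 0 for 10 against 1 µg/ml (969 at an unadjusted p under 0.05), 1405 for 0.1 against 0.01 µg/ml, 35 per 10-fold step and 703 for high against low doses. A minimum of at least 2-fold left 2625, 202, 302, 351, 1219, 0, 168, 10, 519 and 270 genes, which follows from its construction. In fits to only the groups of the comparison, with fewer arrays behind the spread, the counts were 0, 11 and 0 for 10, 1 and 0.1 µg/ml, 0 for 10 against 1 µg/ml, 677 for 0.1 against 0.01 µg/ml, 590 per 10-fold step and 722 for high against low doses. On arrays of one slide only they were 349, 1170, 0 (10 against 1 µg/ml), 1516 (0.1 against 0.01 µg/ml) and 4788 (low doses against day 0). An estimated inter-gene correlation left 67 of 118 list calls.

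Leaving out each array in turn, limma with the spread pooled over groups gave 7120 to 11042 genes for vehicle against day 0, 333 to 1826, 613 to 2707, 296 to 1886 and 3242 to 7375 from the highest to the lowest dose, 0 to 2 for 10 against 1 µg/ml, 1323 to 2734 for 0.1 against 0.01 µg/ml, 394 to 1083 per 10-fold step, 3060 to 6558 for low doses against day 0 and 621 to 1444 for high against low doses; a lone array left in a group was assumed to vary like the others. Directions turned for the p53 targets at 1 µg/ml (adjusted p = 0.69) and the lysosome list between high and low doses (adjusted p = 0.99) with no filter, OMP (0.01) and BEST3 (0.14) at 1 µg/ml with normexp, and PDGFRA at 0.1 µg/ml (-0.03) and LAMB1 at 0.01 µg/ml (-0.01) with the 75th percentile over all probes. As the mean over a gene's probes, ATF3 turned for vehicle against day 0 (-0.08), LAMA1 at 0.1 µg/ml (-0.01), PLK1 at 0.01 µg/ml (0.27) and between high and low doses (-0.17), and SARS1 between high and low doses (0). Except where construction is named, the cause was not tested.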

Other observations

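The negative-control signals and the streak below were looked at after the data had been seen; no explanation was tested for them.

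In vehicle against day 0, probes of the same gene did not always go the same way: of 4573 genes with several tested probes, 178 had probes called in opposite directions, against 72 at 0.01 µg/ml, 9 at 1 µg/ml and 0 at 10 µg/ml against vehicle. Intronic transcripts were lower in vehicle than at day 0 (17 of 26 fell, none rose, median -1.7; camera p = 4.8e-06, and p = 0.055 with an estimated correlation) and fell between 0.01 and 0.1 µg/ml (11 of 26 fell, none rose, median -0.47; camera p = 3.2e-05, and p = 0.076 with an estimated correlation). These p-values are from limma's camera and were not adjusted.

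The genes called in vehicle against day 0 and at 0.01 µg/ml overlapped in the largest number among the doses, as this dose had the most calls: 3974 fell over the 48 h and were higher with ILB than in vehicle (1225.4 by chance), and 1797 rose and were lower (336.5 by chance), with 12 and 5 that moved up or down in both. Part of this overlap may come from the shared vehicle arrays, which were not split because 1 would be left for each comparison. The correlation across genes was -0.88 (-0.55 simulated) and the covariance -0.3141 (-0.0578).

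On ILB 10 replicate 1 a streak of dark spots ran over rows 57 to 185 and columns 91 to 100 of the 384 by 164 spots. Of 391 bright spots inside it, 90 were at least 4-fold below the other arrays and 22 of these were marked as outliers in the scanner file. The rows and columns were taken from all such spots of this array, so 0 lay outside by construction. Without the streak's spots 1435 genes passed at 10 µg/ml. The net signal of negative control spots was 20.4 to 26.3 at 1 µg/ml, against 12.9 to 20 in the other groups. ILB 0.1 replicate 2 had 310 nonuniform spots.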
